A study of Danio rerio with 2 samples.

How the data were processed

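Expression was profiled on 2 Affymetrix zebrafish oligonucleotide arrays, each hybridised with total RNA from 1 pigment cell preparation from the caudal and anal fins of adult wild-type zebrafish. Per the labels' protocols, the fins of 1000 fish bought from a pet shop were digested with trypsin and then collagenase, RNA was prepared on silica columns, and biotin labelling, hybridisation, scanning and MAS 5.0 processing followed Affymetrix's standard procedure at an outside service. The series design says that cells were separated by centrifugation or with a cell sorter, without saying which method gave which sample.

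The authors deposited 1 table of MAS 5.0 signal intensity, on a linear scale with 1 decimal, for 15617 probe sets per array, of which 115 are Affymetrix controls and 15502 measure transcripts. MAS5 is the tool named in the submitters' processing notes; its scaling target and detection calls are not given in the sources used here, and no scanner image or probe-level file was used here. The signals were not brought to a shared target: their means between the 2nd and 98th percentiles were 257 and 192. The precision is limited by the number of arrays, 1 per preparation. The only errors that can be estimated are the disagreement between probe sets of the same gene and the spread between spike-in control probe sets. Both leave out biological and preparation spread.

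Samples were grouped by their titles alone. The title of each sample names the opposite cell type from its source name and cell type fields, so every direction is given as the melanophore-titled array over the xanthophore-titled array, without deciding which label is right. Deposited intensities were used as they stand. Signals under an array's median (47.2 on the melanophore-titled and 43.5 on the xanthophore-titled array) were raised to that median before the log2 ratio, and a ratio against such a floor is a lower bound. List medians take such genes at their bound, and a bound under 2-fold is not counted as within 2-fold. A probe set was compared when its brighter signal reached that array's 75th percentile (234 and 173), and a gene on a list was called measured when its brighter signal reached the array's median. Differences were counted at 4-fold or more, and list members at 2-fold or more. No test between cell types is possible with 1 array each, and none was made.

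Probe sets were named from the platform annotation supplied with the series, with symbols updated through the NCBI gene ID (1 symbol changed): 10795 probe sets had 1 gene symbol, 135 had several and were not named, and 4572 are unnamed here. The named probe sets cover 8793 genes, and a gene with several probe sets took the one with the highest mean log2 signal. The authors' processing kept probe sets open to cross-hybridisation (those with IDs ending in _x_at or _s_at), and leaving them out is one of the alternatives.

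Before the data were examined, 22 gene lists were fixed. They cover melanin synthesis, xanthophore pigment, pteridine enzymes, purine synthesis, pigment lineage regulators, iridophore markers, cell contact genes, Delta and Notch, markers of keratinocytes, connective tissue and bone, erythrocytes, leukocytes, endothelium, Schwann cells and neurons, and skeletal muscle, immediate early and heat shock genes, the cell cycle, ribosomal proteins, the respiratory chain, vacuolar ATPase and lysosome, lipid droplets, and organelle transport. For each list with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 10 bins. This percentile describes these 2 arrays and is not a p-value across replicates. Lists outside the central 95% of random lists are said to stand apart. Genes were named by a rule also fixed beforehand: the 12 largest ratios in each direction among compared genes with a proper symbol, every measured member of the melanin and xanthophore lists, and up to 4 measured members with the largest ratios of each other list. Other genes named in the text were chosen after their values were seen, some as members of a list and some, on no list, for their large ratios (csf1b, thy1, aqp8a.1, slc2a11b, lyve1a, mmp9 and mmp14a).

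Each result was recomputed after quantile normalization, after scaling to equal medians over bright probe sets or over ribosomal protein genes, after removing a lowess trend, with floors at the 25th or 65th percentile or none, with a looser filter on dim probe sets, at 2-fold and 8-fold, with the median over a gene's probe sets and with unmatched random lists. Scaling to the hybridisation spike-ins, scaling to trimmed means, and leaving non-ribosomal genes out of the ribosomal list were added after seeing the data. The calculation was tested on simulated data built from the deposited signals of 15502 probe sets. The noise added had the size seen between compared probe sets of a gene (SD 0.38 on the log2 scale). At 4-fold, 100% of 100 probe sets changed 8-fold, 100% of 100 changed 16-fold and 0% of 15302 unchanged ones were called. Noise this small against a 4-fold threshold could hardly give other rates, so they check only the calculation. They give no error rate for dim probe sets, which were not compared, or between preparations. Of 300 random lists of 10 genes, drawn from 5501 genes, 5% fell outside the central 95%, and 100% of 50 lists raised 2-fold fell above it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.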

Results

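Pigment cells of adult zebrafish fins were profiled on 2 expression arrays, 1 for each of 2 cell types: melanophores, the black cells that make melanin, and xanthophores, the yellow cells that hold pteridine and carotenoid pigments. The comparison the design names is melanophores against xanthophores. The labels disagree on which array is which. The sample titled melanophores carries xanthophores in its source name and its cell type field, and the sample titled xanthophores carries melanophores in both. The arrays are therefore called the melanophore-titled and the xanthophore-titled array, and a direction below is one between titles. There was 1 array per preparation, so no difference has a replicate check. Compared probe sets that report the same gene differed in their log2 ratio with an SD of 0.38 (201 genes with over 1 such probe set), a factor of 1.30. This spread and the range of the spike-in controls below are the only errors given, and both are technical. Of a pair of signals with no direction stated, the melanophore-titled array comes first.

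Signals ranged from 0.2 to 19555 on the melanophore-titled array and from 0.3 to 23427 on the xanthophore-titled array. The melanophore-titled array was the brighter one. Its 18 spike-in control probe sets, for bacterial and phage transcripts that this array type receives in fixed amounts with the hybridisation mix, were all brighter than on the other array, by a median log2 ratio of 0.38 (range 0.18 to 0.97), and the median of the 2929 compared genes was shifted the same way by 0.46. Scaling to the spike-ins lowers each fold towards the melanophore-titled array by a factor of 1.30 and raises each fold towards the xanthophore-titled array by the same factor. The 3 control probe sets along the GAPDH transcript, from its 3′ end to its 5′ end, had log2 ratios of -0.14, -0.07 and -0.09. These differ from each other by less than the spread between probe sets of a gene and would turn positive if ribosomal protein genes were set equal. On both arrays the signal itself fell steeply towards the 5′ end. It was 3844.5, 1707.3 and 422.3 on the melanophore-titled array and 4231.4, 1790.1 and 449.8 on the xanthophore-titled array. The ratios thus show a like 3′ bias on both arrays and not its absence.

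On the melanophore-titled array, the cation/proton exchanger cax1 was 37.7-fold brighter (3161 against 83.8), bco1, which cleaves carotenoids, 32.3-fold (3076 against 95.2), and scarb1, a scavenger receptor that takes up carotenoids, 22.5-fold (2207 against 98.2). The agouti-family signal asip2b followed at 17.7-fold, then phyhd1 at 16.9-fold, the purine enzyme atic at 15.03-fold, clec3ba at 14.1-fold, the tropomyosin tpm4b at 13.9-fold, tagln3b at 13.8-fold, hsd11b1la at 13.8-fold, the calcium sensor hpca at 13.1-fold and the purine enzyme ppat at 12.8-fold. On the xanthophore-titled array, the bone matrix gene spp1 (osteopontin) was 20.6-fold brighter (1215 against 59.1), and the alpha globin hbaa1 was at least 20.3-fold brighter (957 against a signal under the floor). The next largest were enpp1, which makes the mineralisation inhibitor pyrophosphate, at 12.04-fold, the secreted Wnt inhibitor wif1 at 11.9-fold, sccpdha.1 at 11.9-fold, dct, an enzyme of melanin synthesis, at 11.8-fold, the ion exchanger slc24a4a at 9.86-fold, angptl7 at 9.79-fold, the FGF receptor fgfr4 at 8.81-fold, zic2a at 8.49-fold, the thrombospondin thbs4b at 8.05-fold and mxra8a at 7.69-fold. After scaling to the spike-ins cax1 stood at 29.0-fold and spp1 at 26.8-fold. Where the dim signal lay near the floor, the size depended on that floor: raised to the 65th percentile it left bounds of at least 10.3-fold for spp1, 8.11-fold for hbaa1, 6.74-fold for tpm4b, 6.62-fold for ppat and 5.01-fold for dct, and hsd11b1la, angptl7, fgfr4 and zic2a also moved by over 1.5 times.

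Across all compared genes, 109 were 4-fold or more brighter on the melanophore-titled array and 63 on the xanthophore-titled array, of which 9 and 11 are lower bounds, and 72.7% of the compared genes lay within 2-fold. The balance between the 2 directions followed the scaling: 63.4% of the genes that differed 4-fold were brighter on the melanophore-titled array as deposited, and 42.9% (73 against 97 genes) after scaling to the spike-ins. Of the 172 genes that differed 4-fold, 136 still did so in the same direction after scaling to the spike-ins. Over all scalings tried the share ran from 37.4% (equal medians of bright probe sets) to 86.5% (equal median of ribosomal protein genes). Counted by probe set, 171 and 95 of 4269 compared probe sets differed 4-fold. All 9 of the 4-fold genes that had over 1 compared probe set had every such probe set at 2-fold or more the same way. Probe sets too dim to be compared were left out of this check. It therefore says nothing of 4-fold genes such as gch2, zic2a and dlc, whose other probe sets failed the filter. The log2 signals of the 2 arrays correlated across the 15502 transcript probe sets with a Pearson r of 0.91, where probe sets are not independent replicates.

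**Figure D1:**
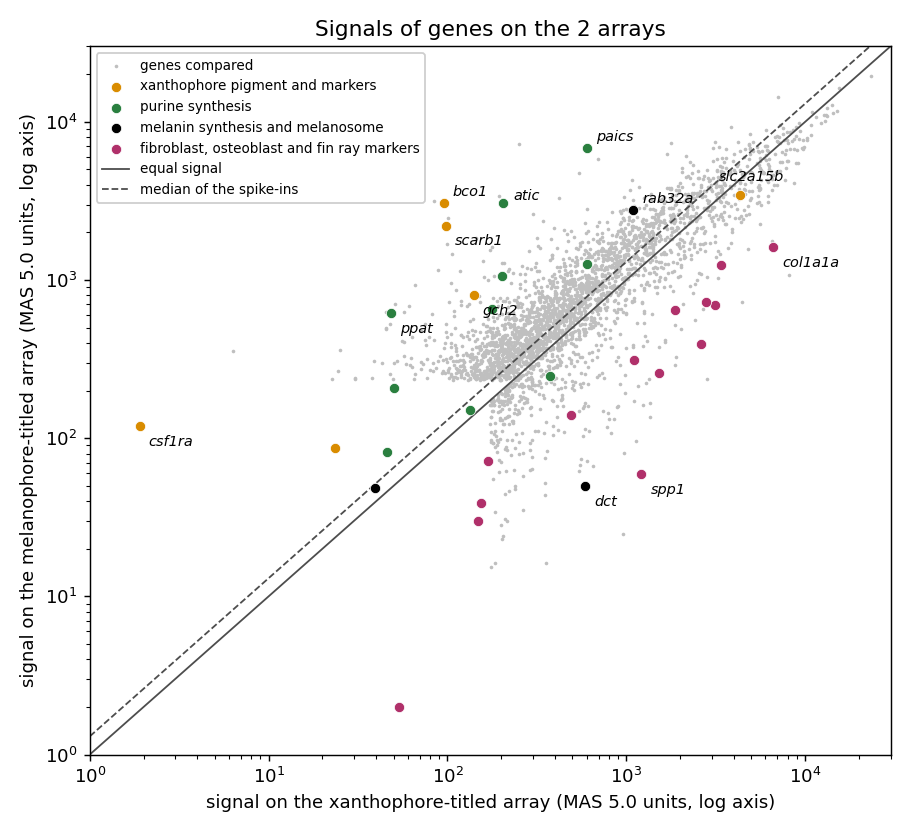
Signal of each compared gene (grey) on the xanthophore-titled array (x axis) and the melanophore-titled array (y axis), in MAS 5.0 units on log axes, with measured members of 4 fixed gene lists in colour. The solid line marks equal signal and the dashed line the spike-ins' median, a factor of 1.30; bco1 and scarb1 lie far above both lines, and dct and spp1 far below.

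Genes of xanthophore pigment were brighter on the array titled melanophores. Of the 17 genes fixed as xanthophore pigment genes and markers, 7 had a named probe set and 6 were measured; 4 of these 6 were 2-fold or more brighter on the melanophore-titled array and none on the other. Beside bco1 and scarb1 they were gch2, the first enzyme of pteridine synthesis in xanthophores, at 5.72-fold (804 against 141), and csf1ra, the receptor xanthophores need, at least 2.73-fold (119 against 1.9, which is under the floor). As csf1ra is also a macrophage gene, it was kept off the leukocyte list. With the floor at the 65th percentile csf1ra was bound only to at least 1.27-fold, and it was also under 2-fold with bright probe sets set to equal medians; bco1, scarb1 and gch2 kept 2-fold under every alternative run. The transcription factor pax7a stood at 86.7 against 23.4, at least 1.99-fold, and the sugar transporter family member slc2a15b at 3444 against 4349. The list's median log2 ratio was 1.98, above those of all 10000 random lists. Endothelial markers were brighter on the same array (median 1.49). In the wider pteridine and tetrahydrobiopterin list, 2 of 4 measured members were 2-fold brighter on the melanophore-titled array. These were gch2 and mycbp2 (2.38-fold, and 1.83-fold after scaling to the spike-ins), a ubiquitin ligase gene and not an enzyme of this route. The enzymes pcbd1 and qdprb.1 lay within 2-fold. The median of 0.98 (93.0th percentile), which includes mycbp2, did not stand apart.

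Few melanin genes were measured. Of the 18 fixed genes of melanin synthesis and the melanosome, 5 had a named probe set and 3 were measured, with ratios that went both ways. Dopachrome tautomerase, dct, was 11.8-fold brighter on the xanthophore-titled array (590 against 50.1), the small GTPase rab32a was 2.52-fold brighter on the melanophore-titled array (2752 against 1091; 1.94-fold after scaling to the spike-ins), and tyrosinase, tyr, lay near the floor on both (48.4 against 39.2). The list's median of 0.15 lay at the 44.3rd percentile of random lists. After scaling to the spike-ins tyr fell under the filter and the list had too few measured members for a percentile. Connective tissue and bone genes were brighter on the same array as dct (median -1.81).

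Purine synthesis genes were brighter together on the melanophore-titled array. De novo purine synthesis supplies GTP, from which pteridines are made, and also guanine. Which of these uses the genes served was not tested. Of 10 measured members, 7 were 2-fold or more brighter there and none on the other array, and the median log2 ratio of 1.97 lay above all 10000 random lists. The largest were atic and ppat, given above, paics at 11.3-fold (6828 against 602) and impdh1b at 5.25-fold; gart stood at 4.15-fold (at least 2.24-fold with the floor at the 65th percentile) and adsl at 3.71-fold. The second IMP dehydrogenase, impdh2, ran the other way, at 246 against 372. Of the lipid droplet and lipoprotein genes, which include scarb1, 4 of 5 measured members were 2-fold brighter on the melanophore-titled array, among them the fatty acid binding protein fabp3 (2.66-fold), apoeb (2.35-fold) and the lipid droplet coat gene plin3 (2.08-fold). The list's median of 1.23 lay at the 99.6th percentile. After scaling to the spike-ins 6 of 10 purine genes and 2 of 5 lipid genes were 2-fold brighter there. Both lists still stood apart, but this scaling shifts every ratio alike, random lists included, so it could hardly move their percentiles. After it apoeb and plin3 stood at 1.80-fold and 1.60-fold. The ratio of fabp3 fell under 2-fold with quantile normalization, equal bright medians or trimmed means.

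Connective tissue and bone genes were brighter together on the xanthophore-titled array. Of 14 measured fibroblast, osteoblast and fin ray markers, 13 were 2-fold or more brighter there and none on the other array. The list's median log2 ratio was -1.81, below all 10000 random lists. Beside spp1, the collagen col10a1a was 6.65-fold brighter (2606 against 392), the matrix metalloproteinase mmp2 5.89-fold (3.76-fold as the median of its 2 probe sets), col1a2 4.47-fold (3114 against 697) and col1a1a 4.09-fold (6611 against 1616). The globins went the same way, with hbaa1 as above and hbae3 at 184 against 87.7 (1.51-fold with ribosomal protein genes set equal, and under 2-fold with the higher floor), but only 2 of 10 erythrocyte markers were measured. Endothelial markers ran in the other direction: 4 of 5 measured members were 2-fold brighter on the melanophore-titled array. These were kdrl at 4.34-fold, plvapb at 4.17-fold, fli1 at 2.82-fold and fli1rs at least 2.53-fold. The list's median of 1.49 lay at the 99.9th percentile. After scaling to the spike-ins 3 of 5 were 2-fold brighter there, without fli1rs. With the higher floor fli1rs lay under the floor on both arrays, so its value of 1.26-fold is only the ratio of the 2 floors.

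Keratinocyte markers were similar on both arrays. Of 14 measured members, 10 lay within 2-fold and 2 have only a lower bound under 2-fold, the median was 0.07 (15.8th percentile), and krt8 stood at 11558 against 10947. The basal keratin krt5 was 2.96-fold and the claudin cldnb at least 2.80-fold brighter on the melanophore-titled array, while agr2 stood 1.82-fold towards the xanthophore-titled array and krt94 at least 1.81-fold towards the melanophore-titled array. With the floor at the 65th percentile cldnb was bound only to at least 1.30-fold. Leukocyte markers went both ways. The antigen presentation genes cd74b (2.79-fold) and cd74a (2.44-fold; 1.87-fold after scaling to the spike-ins) were brighter on the melanophore-titled array and the chemokine receptor cxcr4b at least 2.42-fold on the xanthophore-titled array. The actin regulator coro1a stood at 126 against 64.2. The leukocyte median of -0.47 lay at the 0.1th percentile. With a floor at the 65th percentile of each array it lay at the 49.8th. Its median of 0.33 there is the log2 ratio of the 2 floors, the value given to any gene under both. The ratio of cxcr4b (40.9 against 114.4) turned only because its dimmer signal was raised to a floor above the brighter one. Neither is a change of direction in the signals. With ribosomal protein genes set equal the leukocyte median was 0.0098 and cxcr4b was under 2-fold. Schwann cell and neuron markers did not stand apart (median 0.41 over 5 measured, 65.7th percentile; uchl1 stood at 3022 against 2262). Of the muscle markers 1 of 13 was measured, actc1b at 75.4 against 86.9, and of the iridophore markers 2, crip2 at 1079 against 735 and ednrba at 88.9 against 84.9; neither list allowed a percentile.

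**Figure D2:**
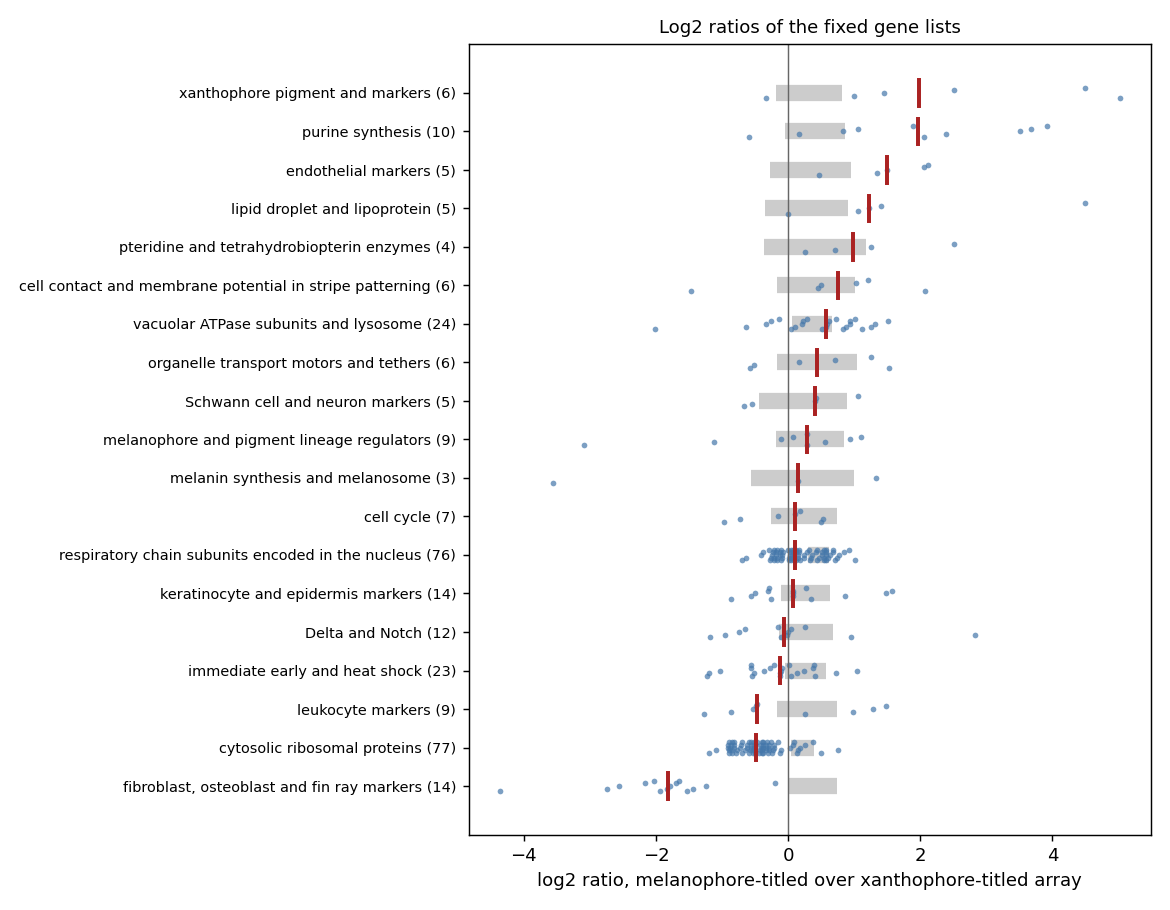
Log2 ratio, melanophore-titled over xanthophore-titled array (x axis), of the measured members (blue points, number in brackets) of the 19 gene lists with at least 3 measured members. Red bars mark each list's median and grey bars the central 95% of the medians of 10000 random lists; the xanthophore and purine lists lie to the right of their grey bars and the connective tissue list to the left.

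Of 9 measured regulators of the pigment lineage, 5 differed by less than 2-fold. The transcription factors sox10 (3857 against 3177), tfap2a (2604 against 2144) and mitfa (358 against 243), were among them; the log2 ratios of sox10 and tfap2a, both 0.28, were both -0.10 after scaling to the spike-ins. The exceptions were foxd3, 2.15-fold brighter on the melanophore-titled array as deposited and 1.65-fold after scaling to the spike-ins, and zic2a (8.49-fold) and snai2 (2.17-fold; 1.56-fold with ribosomal protein genes set equal), brighter on the xanthophore-titled array. The ratio of sox9b is only a bound, at least 1.91-fold towards the melanophore-titled array, and the list's median was 0.28 (35.4th percentile).

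Genes listed for cell contact or stripe patterning split by member. The epithelial cadherin cdh1 was 4.20-fold brighter on the melanophore-titled array (1949 against 464) and the neural cadherin cdh2 2.77-fold brighter on the xanthophore-titled array (441 against 159; 1.99-fold with ribosomal protein genes set equal). The gap junction gene gja1b, at 1871 against 921, and the spermine synthase sms, at 186 against 80.2, were 2.03-fold and 2.32-fold brighter on the melanophore-titled array, but 1.56-fold and 1.78-fold after scaling to the spike-ins. The list's median of 0.76 (87.4th percentile) did not stand apart. Its 6 measured members include sms, which is a polyamine enzyme and not a contact gene. In the Delta and Notch list, the ligand dlc was 7.13-fold brighter on the melanophore-titled array (407 against 57.0; at least 4.35-fold with the floor at the 65th percentile) and the Hes-family repressor her9 2.27-fold brighter on the xanthophore-titled array (1.63-fold with ribosomal protein genes set equal), while jag1b (97.9 against 190) lay within 2-fold and mib1 was at least 1.92-fold brighter on the melanophore-titled array. The receptor notch2 stood at 1808 against 2004. Of 12 measured members 7 lay within 2-fold and 3 have only a lower bound under 2-fold, and the median of -0.06 lay at the 5.42th percentile; 4 members, jag1b among them, were 2-fold brighter on the xanthophore-titled array after scaling to the spike-ins.

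Of 23 immediate early and heat shock genes, which tissue dissociation induces, 18 lay within 2-fold and 1 has only a lower bound under 2-fold; hspb1 (2.34-fold), gadd45bb (2.29-fold) and egr1 (2.03-fold) were brighter on the xanthophore-titled array and hspb8 (2.06-fold; 1.58-fold after scaling to the spike-ins) on the other. The list's median of -0.12 lay at the 1st percentile and turned to 0.36 with ribosomal protein genes set equal, where hspb1, gadd45bb and egr1 stood at 1.68-fold, 1.65-fold and 1.46-fold. Cytosolic ribosomal protein genes, taken by symbol pattern, had a median of -0.49, below all 10000 random lists, with 75 of 77 within 2-fold; rpl28 (2.29-fold) and rpl30 (2.12-fold) were brighter on the xanthophore-titled array, followed by rps3a (1.89-fold) and rpl17 (1.87-fold). With these genes set equal rpl28 and rpl30 stood at 1.64-fold and 1.53-fold, and after scaling to the spike-ins 23 of the 77 were 2-fold brighter on the xanthophore-titled array and the median was -0.87. Nuclear genes of the respiratory chain had a median of 0.10 against 0.47 for random lists of their brightness, below all 10000, with 75 of 76 within 2-fold and ndufa12 (2.01-fold), ndufb10 (1.90-fold), uqcrb (1.80-fold) and atp5mf (1.70-fold) as the largest, all towards the melanophore-titled array. After scaling to the spike-ins the respiratory median turned to -0.28, at the 0.01th percentile, and ndufa12 stood at 1.54-fold.

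The vacuolar ATPase and lysosome list did not stand apart (median 0.58, 91.9th percentile), and went both ways: the cysteine protease ctsk, an osteoclast enzyme, was 4.02-fold brighter on the xanthophore-titled array, and the pump subunits atp6v1b2 (2.86-fold), atp6v1c1a (2.48-fold) and atp6v0cb (2.37-fold) on the melanophore-titled array. After scaling to the spike-ins, atp6v1b2 alone of the 24 was 2-fold brighter there, at 2.19-fold, and with the floor at the 65th percentile its bound was 1.61-fold. Organelle transport genes had a median of 0.43 (45.2nd percentile), with dynll2b at 2.87-fold and rab11a at 2.39-fold (1.83-fold after scaling to the spike-ins) brighter on the melanophore-titled array and dynll1 (1.63-fold) and dctn2 (1.49-fold, towards the other array) within 2-fold. Of 7 measured cell cycle genes 5 lay within 2-fold as deposited, 2 have only a lower bound under 2-fold, and mcm4 and mcm2 passed 2-fold towards the xanthophore-titled array after scaling to the spike-ins (median 0.11, 29.8th percentile). The signals included pcna, at 1903 against 1344, mcm4, at 60 against 117, mcm2, at 82.1 against 135, and mcm3, at 62.5 against a signal under the floor; the other 10 named cell cycle genes were under the median of both arrays. The remaining neural genes named by the rule, mbpa (at least 2.09-fold towards the melanophore-titled array; 1.60-fold after scaling to the spike-ins), stmn2a (54.6 against 86.6) and gap43 (54.2 against 78.9), were all dim. Of the 19 lists with a percentile, 9 stood apart, where lists of genes drawn independently would give 0.95. Genes of a list can vary together within a preparation, and lists share genes such as scarb1 and gch2. The 0.95 is therefore no measure of how many would stand apart between any 2 preparations.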

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

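Scaling to the spike-ins and to trimmed means and the shortened ribosomal list were chosen after seeing the data. Of 226 list percentiles under alternatives, 221 kept their side of the thresholds. Scaling by 1 factor per array shifts every log2 ratio alike, random lists included, so there percentiles can move only through the filter on measured genes. Of 206 list medians 70, and of 1056 ratios of named genes 445, moved by more than the spread between probe sets. A further 8 medians and 1 ratio turned, counted only for lists that stood apart and genes at 2-fold or more as deposited. Other values changed sign too, such as the keratinocyte median (0.07 as deposited, -0.31 after scaling to the spike-ins). Percentiles ran from 99.99 to 100 for the xanthophore list, 99.7 to 99.98 for the endothelial, 99.02 to 99.7 for the lipid, 0.13 to 1.84 for the immediate early and 0 to 0.27 for the respiratory list, and stayed at 100 for purine synthesis and 0 for the connective tissue and ribosomal lists. With a floor at the 65th percentile the leukocyte list no longer stood apart (49.8th). Its median there, 0.33, is the log2 ratio of the 2 floors, and the value of 0.043 for cxcr4b was set by the raised floor. Both are counted above as turned, but neither is a change of direction in the signals. With this floor the Delta and Notch (1.82nd) and keratinocyte (1.93rd) lists came to stand apart. Delta and Notch did so too after quantile normalization (1.22nd) and without the lowess trend (1.81st). Why the Delta and Notch and keratinocyte lists moved was not tested. The melanin list kept too few measured genes for a percentile under some scalings. Scaling moved the counts of 4-fold differences, because it shifts every gene; the pairs here give the melanophore-titled side first. By probe set they were 98 and 161 (quantile), 91 and 158 (equal bright medians), 361 and 48 (ribosomal), 98 and 164 (lowess), 105 and 151 (spike-ins), and 97 and 155 (trimmed means). By gene they were 66 and 103, 61 and 102, 212 and 33, 65 and 106, 73 and 97, and 66 and 100, in the same order. At 2-fold, 999 and 269 probe sets and 619 and 181 genes differed, at 8-fold 45 and 20 probe sets and 31 and 12 genes, and with the 65th percentile floor 134 and 60 probe sets and 88 and 44 genes. The respiratory median turned to -0.33 (quantile), -0.35 (equal bright medians), -0.33 (lowess), -0.28 (spike-ins) and -0.32 (trimmed means). Scaling to ribosomal genes turned the immediate early median to 0.36 and the leukocyte median to 0.0098, since it shifts every ratio upwards. Of the 68 named genes at 2-fold or more, 51 to 58 stayed there under each of the scalings and without the lowess trend (53 with the spike-ins), and 60 with the 65th percentile floor, where atp6v1b2, cldnb, csf1ra, cxcr4b, fli1rs, hbae3, mbpa and sms were lost and 22 of 96 ratios moved by over 1.5 times. Ribosomal scaling lost cdh2, cxcr4b, egr1, gadd45bb, hbae3, her9, hspb1, rpl28, rpl30 and snai2. Spike-in scaling lost apoeb, atp6v0cb, atp6v1c1a, cd74a, fli1rs, foxd3, gja1b, hspb8, mbpa, mycbp2, ndufa12, plin3, rab11a, rab32a and sms, and the other scalings lost most of these besides fabp3 and, with equal bright medians, csf1ra. The other floors, probe set rules and collapse by median lost none, though mmp2 moved to 3.76-fold with the last. Signals under an array's median give only bounds. With 1 array per preparation, leaving out a replicate was not possible. No paired analysis was possible because each group has 1 array.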

Other observations

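The FGF, Wnt, Rab, glycolysis, proteasome, translation factor and further matrix groups, the shortened ribosomal list, and all tests except those of the labels were chosen and tested only after the largest ratios had been seen. The FGF and Wnt groups were made after fgfr4 and wif1 had been seen among the largest ratios, so their percentiles are also given without these. All 4 measured FGF ligands and receptors were 2-fold or more brighter on the xanthophore-titled array, among them fgfr4 at 8.81-fold, fgfr3 at 5.52-fold and fgfr2 at 3.25-fold, and the group's median log2 ratio of -2.08 lay at the 0.01th percentile of random lists (-1.70 and 0.045th over the 3 others). Of 18 measured Wnt pathway genes, 7 were 2-fold brighter on the xanthophore-titled array, among them wif1, fzd8a (4.65-fold), fzd9b (4.58-fold) and fzd7a (4.05-fold), and 2 on the other, of which the transcription factor lef1 stood at 6.72-fold; the median was -0.17 (0.15th percentile; -0.06 and 1.06th without wif1), and 8 lay within 2-fold. The ligand csf1b was 7.58-fold brighter on the xanthophore-titled array (557 against 73.4), while its receptor csf1ra was brighter on the melanophore-titled one. With the floor at the 65th percentile fgfr2 was bound only to 1.52-fold, fzd9b to 2.46-fold, fzd8a to 2.52-fold and csf1b to 4.72-fold.

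Of 30 measured Rab GTPases, 9 were 2-fold brighter on the melanophore-titled array and none on the other. The largest was rab10 at 6.92-fold (2356 against 340). The median of 0.70 lay at the 99.6th percentile. The group holds rab32a and rab11a, already seen on fixed lists, and no percentile was computed without them. After scaling to the spike-ins 1 of 30 was 2-fold brighter on the melanophore-titled array and the percentile was 99.5. Other single genes, picked for their ratios, were brighter there: thy1 at 8.35-fold (5787 against 693), the aquaporin aqp8a.1 at 7.85-fold (3297 against 420), slc2a11b at 6.17-fold and lyve1a, a marker of lymphatic endothelium, at 10.9-fold (at least 5.34-fold with the floor at the 65th percentile). The matrix proteases mmp14a (7.61-fold) and mmp9 (6.11-fold), picked likewise, were brighter on the xanthophore-titled array. Glycolysis genes (median 0.41, 43.6th percentile) and proteasome subunits (0.58, 84.9th) did not stand apart, and translation factors (0.13, 2.89th) lay just inside the range. The 73 ribosomal protein genes without the S6 kinases and rps19bp1, which the symbol pattern took in, had a median of -0.50, below all random lists.

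The title and the cell type field of each sample name opposite cell types, and 3 readings were set out before the values were seen. That the titles are right and the other fields swapped is argued against by the xanthophore list, which stood at the 100th percentile towards the melanophore-titled array, where this reading puts it at or under the 2.5th. A like mixture of both cells on each array is argued against by the same list's median of 1.98, where it would need 1 or less. That the source and cell type fields are right and the titles swapped has the xanthophore list on its side. The melanin list that it also needs lay at the 44.3rd percentile, on 3 measured genes, so the test cannot settle it. Of these, dct alone, at 11.8-fold (5.01-fold to 16.2-fold over the alternatives), points that way. The second, rab32a, was 2.52-fold brighter on the melanophore-titled array, and tyr lay near the floor on both. Connective tissue and bone genes were brighter on the same array as dct. The melanophore-titled array may therefore hold xanthophore RNA, and this stays a hypothesis until the submitters' records are checked.

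More genes were 4-fold brighter on the melanophore-titled array than the reverse, which may follow from array brightness, since the deposited signals share no scaling target. All 18 spike-ins were brighter on that array. Scaling to them gave a share of 42.9% in place of 63.4%, but it lowers every log2 ratio by the same amount, so that move is no test of the cause, and setting ribosomal protein genes equal gave 86.5%. Quantile normalization (39.1%), equal bright medians (37.4%), removing the lowess trend (38.0%) and trimmed means (39.8%) also lowered the share. These bring the 2 arrays to like signals by design, so they are no test of the cause either. Only the ribosomal reference raised the share, and that list itself stood apart. The cause stays open, and no biological explanation was tested.

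Connective tissue and bone genes, with col1a1a at 6611 against 1616 and sparc at 3379 against 1250 (1.94-fold with ribosomal protein genes set equal), were brighter on the xanthophore-titled array. A lower share of the main cell type that raises every other cell type alike is argued against by the keratinocyte list. Its median lay 1.88 above that of the connective tissue list on the log2 scale, and 13 of 14 measured connective tissue members lay under the lowest of 14 keratinocyte members (agr2, -0.86). This covers only other cells in the same proportions in both preparations. A lower share of the main cell type with a different mix of other cells was not tested. A larger share of connective tissue and bone cells stays open: 37 other measured matrix genes had a median of -0.50, below all random lists, with 11 at 2-fold or more that way, short of the -1 set for it; after scaling to the spike-ins it was -0.88 with 17. That group leaves out thbs4b, mmp9 and mmp14a, already seen as large, and with them the median was -0.57. That the pigment cells make these transcripts themselves cannot be told apart from it, because the median of sox10, tfap2a and mitfa lay close to the median gene (log2 difference -0.18) and 1 array per preparation holds both the cell type and its purification. The labels do not say which sample was centrifuged or sorted.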
